A study of Homo sapiens with 11 samples.

How the data were processed

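The assay measured 5-hydroxymethylcytosine (5-hmC), the oxidised form of 5-methylcytosine made by the TET enzymes, in DNA of human erythroid cultures grown from CD34+ stem and progenitor cells. Per the labels' protocols, the DNA was sheared, 5-hmC was tagged with an azide-bearing glucose by a glucosyltransferase, biotin was attached by click chemistry, and tagged fragments were captured on streptavidin and sequenced. The cultures were kept at 21% oxygen (normoxia) or 1% oxygen (hypoxia). The labels give bone marrow as the source in one field and mobilised blood in another, and the source is therefore left open here. Of the 11 samples, 10 have values: normoxia on days 0, 3, 7 and 10 with 1 library a day, and hypoxia on days 3, 7 and 10 with 2 libraries a day. The input sample was not analysed here, so no background was subtracted.

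The deposited values are FPKM per region, reads scaled to the length of the region in kilobases and to the total reads of the library, per the file headers. The submitters' processing notes name BWA 0.7.17, MACS2, HTSeq and the build hg19, without saying what each was used for. The 4 normoxia files and the 3 files of hypoxia replicate 1 list 420143 common regions covering 212 Mb, with a median length of 378 bp. The 3 files of hypoxia replicate 2 list 632474 other regions covering 323 Mb, with a median length of 363 bp, and 6 regions have the same coordinates in both sets. How either set was called is not given in the sources used here. The column headers of 2 hypoxia replicate 1 files, those of days 7 and 10, name normoxia. The headers of the normoxia files of those days name normoxia too, so the headers do not themselves describe an exchange. The series' own record of which file belongs to which sample was followed, and both files differ in their values from the normoxia files of the same day.

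FPKM multiplied by region length came out as a whole multiple of a single step in 100% of the regions above 0 in every library, with a tolerance of 0.01 read. Whole reads and library totals were worked out from that step. The totals came to 18812457 to 21164180 reads in the 7 libraries of the common set and 70460001 to 81500007 in the 3 libraries of hypoxia replicate 2. The median region held 3 to 5 reads in the common set and 19 to 30 reads in hypoxia replicate 2. Shares of reads carry 95% Wilson intervals and pooled levels carry 95% Poisson intervals. Both cover counting error only, because reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 reads, which is 0.375 to 0.422 FPKM for a region of median length in the common set.

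Genes were the unit planned before the data were examined. No annotation of hg19 was used here, and coordinates of another build cannot stand in for it, so gene values, the gene lists fixed beforehand, shares in promoters and gene bodies, and gene names are not reported. Windows of 100 kb took the place of genes, as the unit in which both region sets can be joined. A window's value is the length-weighted mean FPKM of the regions whose midpoint lies in it. Chromosomes 1 to 22 and X were used.

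Windows were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 0.1), keeping the 24119 windows above 0 in at least 3 of the 9 libraries of days 3, 7 and 10. Fold changes are on that scale, which understates the change of low windows. The model held day, oxygen and a term for hypoxia replicate 2, with 4 residual degrees of freedom. The term absorbs the difference between the region sets, so the mean oxygen effect rests on the 6 common libraries. Oxygen by day was tested with a moderated F over both interaction terms, and oxygen at each day with contrasts of that fit, which has 2 residual degrees of freedom and a prior of 18.6. With 1 normoxia library a day, that library is fitted exactly and is assumed to vary like the hypoxia libraries, from which the residual spread of this fit comes. Single regions were tested in the 6 common libraries with day and oxygen, because the sets share almost no coordinates; 367673 regions were kept and 2 residual degrees of freedom remained. Adjusted p-values are from the Benjamini-Hochberg method with a threshold of 0.05, and all tests are two-sided. Nothing in the labels says that libraries of a group came from separate cultures or donors, so p-values measure the spread between these libraries.

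The numbers of the hypoxia replicates were checked for pairing. Differences between replicate 1 and replicate 2 in the windows correlated between days at 0.53 (days 3 and 7), 0.48 (days 3 and 10) and 0.75 (days 7 and 10). The separate region sets could give such correlations, and they cannot be told apart here from a pairing of the libraries. The term for replicate 2 was part of the planned design.

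Regions of the common set were matched to those of hypoxia replicate 2 with bedtools 2.31.1 at a reciprocal overlap of 50%, keeping the largest overlap. The 156641 pairs were classed by the change from day 3 to day 10 in hypoxia replicate 2 as gained (log2 change of 1 or more), lost (-1 or less) or in between. Class levels are reads summed over the class and scaled to FPKM by its summed length. Regions were also counted by a rule of size, a change of 2-fold or more with at least 20 reads in the pair of libraries, beside the count that Poisson sampling of unchanged regions gives. Windows named for oxygen and for day 10 against day 3 follow a rule fixed for genes: where none passed the threshold, the 5 each way with the smallest p. Windows named for single days, for oxygen by day, and single regions named by class were chosen after their values were seen.

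The fits were tested on simulated reads with 100 windows changed by each size, out of 24119. For oxygen, 5% of the windows changed by a log2 of 1 and 43% of those changed by 2 were recovered. The figures were 6% and 61% for day 10 against day 3, 3% and 20% for oxygen by day, and 3% and 35% for oxygen at day 10. Unchanged windows were also called, 3 for oxygen, 2 for day 10 against day 3, 12 for oxygen by day and 23 for oxygen at day 10. For single regions, 0% of those changed by a log2 of 2 and 0% of those changed by 4 were recovered among 367673, so a count of 0 from that test says little. Alternatives covered the replicate term, the pseudocount, filters, scaling and each library left out. Window size, a minimum of 5 kb of regions, voom in limma on the whole reads, an exchange of normoxia and hypoxia replicate 1 on days 7 and 10, and the alternatives for the shares and region classes were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.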

Results

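The series followed 5-hmC through erythroid differentiation at 21% and 1% oxygen. Cultures of CD34+ progenitors, which become red cell precursors in the presence of erythropoietin, were sampled in normoxia on days 0, 3, 7 and 10 and in hypoxia on days 3, 7 and 10. Each normoxia day has 1 library. Each hypoxia day has 2, numbered replicate 1 and replicate 2. Normoxia and hypoxia replicate 1 were measured over 420143 common regions with 18812457 to 21164180 reads a library. Hypoxia replicate 2 was measured over 632474 other regions with 70460001 to 81500007 reads, so its levels cannot be set directly against those of the other libraries. All coordinates are hg19. The regions carry no gene names in the files, and no annotation of that build was used here. Values given per library have no replicate check.

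The share of reads inside the common regions was highest in the starting cells. It was 39.0% (95% Wilson interval 38.97 to 39.02%) in normoxia on day 0, 19.2% on day 3, 14.3% on day 7 and 10.4% on day 10. In hypoxia replicate 1 the share was 16.1% on day 3, 20.4% on day 7 and 17.2% on day 10. Hypoxia was thus 3.19 points below normoxia on day 3, and 6.13 and 6.79 points above it on days 7 and 10. The counting intervals of these shares do not overlap, but each compares single libraries. Untargeted background reads also fall inside regions, and without an input their part of each share was not measured. It can weigh most where the share is smallest, in normoxia on day 10. An exact sign-flip test over the 3 days gave p = 0.5 for the mean difference of 3.24 points (SD 5.58, n = 3), where the smallest p the design allows is 0.25. In hypoxia replicate 2 the share in its own regions was 57.1%, 58.6% and 52.9%, of library totals that may be rounded.

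**Figure D1:**
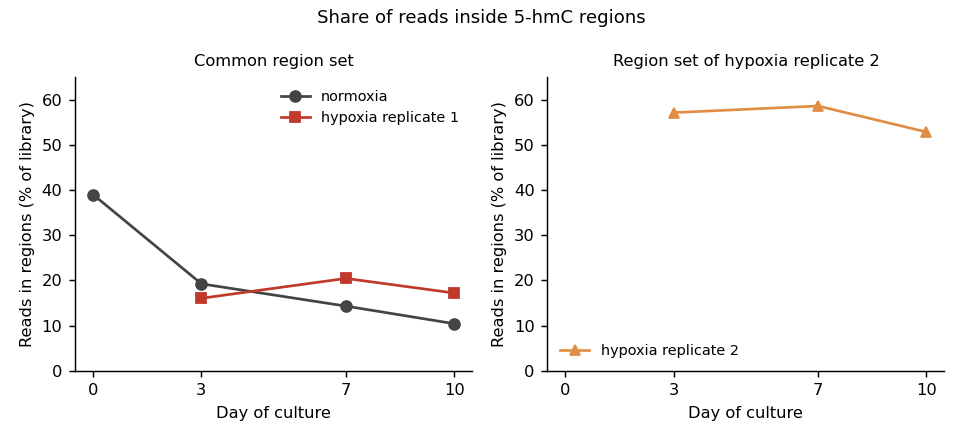
Percent of each library's reads that fall inside 5-hmC regions (vertical axis) by day of culture (horizontal axis), 1 point per library, with counting intervals smaller than the points. Normoxia goes from 39.0% to 10.4%, hypoxia replicate 1 lies below it on day 3 and above it on days 7 and 10, and hypoxia replicate 2 is shown apart because its regions differ.

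The first question was how the 5-hmC signal in regions changes over the days of normoxia. The 104425 regions with the highest day 0 level were at 3.66 FPKM on day 0, 1.38 on day 3, 0.717 on day 7 and 0.392 on day 10, and their share of all reads went from 30.0% to 3.22%. The 104425 regions with the lowest day 0 level were at 0.0544 FPKM on day 0, 0.308 on day 3 and 0.349 on day 10. Both sets were ranked on the day 0 library itself, so part of their change from day 0 reflects that selection. By the rule of size, 102013 of 125627 regions were at least 2-fold lower on day 10 than on day 0 and 4133 were at least 2-fold higher, where Poisson sampling alone gives 2218 and 2460. The counted regions as a whole were shifted by a median log2 of -2.65, and the counts contain that shift. The 41770 longest common regions, over 871 bp each, were at 3.19 FPKM on day 0 and 0.446 on day 10, against 1.31 and 0.490 in the rest. These are values of 4 single libraries and carry no test. No spike-in or input was used, so a falling yield of the pull-down cannot be told apart here from a loss of 5-hmC.

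The second comparison was between days 3, 7 and 10 across both oxygen levels. The smallest p-values for day 10 against day 3 belonged to windows with a lower 5-hmC signal on day 10. Of the 5 lower windows named by the rule, 4 lie side by side on chromosome 1, from 2700001 to 3100000. In the window from 3000001 to 3100000, 72.5 kb of regions were at 4.40 FPKM in normoxia on day 0, at 2.21 on day 3 and at 0.240 on day 10. The same window was at 1.24 and 0.50 FPKM in hypoxia replicate 1 on days 3 and 10, and at 2.79 and 0.543 in hypoxia replicate 2. Its log2 fold change was -2.03 ± 0.30 (SE; limma, adjusted p = 0.0973), and it was lower in each of the 3 series. The window at 2700001 to 2800000 had a log2 fold change of -2.08 ± 0.30 and went from 2.35 to 0.253 FPKM in normoxia. The 5 windows named for higher values on day 10 held 0.298 to 1.276 kb of regions. The window from 17600001 to 17700000 on chromosome 11, with 0.983 kb of regions, was at 0.734 and 1.90 FPKM in normoxia on days 3 and 10, at 0.496 and 3.56 in hypoxia replicate 1, and at 1.16 and 4.95 in hypoxia replicate 2 (log2 fold change 1.96 ± 0.30, limma adjusted p = 0.0973).

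None of these windows passed the threshold. In limma, 0 of 24119 windows differed between days 10 and 3, with 5242 at an unadjusted p under 0.05, and 0 differed between days 7 and 3, with 2962 at an unadjusted p under 0.05 (voom also 0). The count for day 10 against day 3 was 4650 with voom on the reads (193 higher, 4457 lower), 320 among windows with at least 5 kb of regions in both sets (8 higher, 312 lower), 1370 without the day 3 library of hypoxia replicate 1 (36 higher, 1334 lower), 15 without the normoxia day 3 library (10 higher, 5 lower) and 1, higher, without that of day 10. The count for day 7 against day 3 was 834 without the normoxia day 3 library (758 higher, 76 lower) and 50 without that of day 10 (41 higher, 9 lower). With normoxia and hypoxia replicate 1 exchanged on days 7 and 10, where 2 hypoxia files are headed normoxia, the 2 counts were 1324 (50 higher, 1274 lower) and 44 (10 higher, 34 lower). Over all windows the median log2 fold change of day 10 against day 3 was -0.37.

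The deeper hypoxia replicate 2 libraries showed loss and gain side by side. By the rule of size, 223461 of 509847 regions were at least 2-fold lower on day 10 than on day 3 and 73415 were at least 2-fold higher, where Poisson sampling alone gives 3239 and 3886. Day 10 differed from day 7 by as much in fewer regions, 45605 lower and 9167 higher of 434080. The counted regions as a whole were shifted by a median log2 of -0.78 against day 3 and -0.29 against day 7, and the counts contain those shifts. The day 3 library of this replicate stood apart from its later ones. Across regions it correlated with day 10 at 0.208, while day 7 correlated with day 10 at 0.836 (Spearman). The counts against day 3 rest on that single library. Single regions chosen after their values were seen illustrate both directions. The region at 37413217 to 37413734 on chromosome 6 was at 0.467, 10.1 and 13.4 FPKM on days 3, 7 and 10 in hypoxia replicate 2, at 0.376, 4.34 and 3.28 in hypoxia replicate 1, and at 0.557, 4.26 and 1.39 in normoxia. The region at 238364240 to 238365270 on chromosome 2 was at 3.24, 0.549 and 0.228 FPKM in hypoxia replicate 2. In hypoxia replicate 1 it was at 0.284, 0.557 and 0.0458, so it was already low there on day 3. In normoxia it was at 7.27 on day 0 and 2.52, 0.333 and 0 on the later days.

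The classes drawn from hypoxia replicate 2 were then read in the other series. Of the 156641 matched regions, 84728 were lost, 12134 gained and 59779 in between. These classes rest on the day 3 library of hypoxia replicate 2. Across matched regions it correlated at 0.467 with normoxia on day 0 and at 0.0831 with hypoxia replicate 1 on day 3 (Spearman). The classes may thus reflect that library as well as the day. Lost regions were at 2.97 FPKM in normoxia on day 0 and at 1.01, 0.399 and 0.275 on days 3, 7 and 10, while in hypoxia replicate 1 they were at 0.625, 0.586 and 0.465. Gained regions were at 1.42 FPKM on day 0 and at 1.04, 1.64 and 0.890 in normoxia, against 0.985, 2.94 and 2.23 in hypoxia replicate 1. Regions in between were at 2.66 FPKM on day 0, then at 1.25, 0.841 and 0.490 in normoxia and at 0.922, 1.44 and 1.13 in hypoxia replicate 1. The widths of the counting intervals are small beside these differences, for example 0.885 to 0.895 FPKM for gained regions in normoxia on day 10. The ratio of gained to lost regions was 1.03, 4.13 and 3.24 in normoxia on days 3, 7 and 10, and 1.58, 5.01 and 4.79 in hypoxia replicate 1. It was higher in hypoxia on 3 of 3 days, by a mean log2 of 0.49 (SD 0.18, n = 3, exact sign-flip test, two-sided p = 0.25, the smallest possible). Evenly spread background reads draw such a ratio toward 1, and normoxia had the smaller share of reads in regions on days 7 and 10. On those days 1 line nearly joined the 3 class levels of the 2 libraries (upper over lower slope 1.03 and 1.12). Background could thus give much of the difference on days 7 and 10. It need not be the only cause, since regions classed by day 0 level did not lie on 1 line (ratios of slopes -0.139 and -2.43). On day 3 the share was larger in normoxia. The ratio of gained regions to those in between was higher in hypoxia by a log2 of 0.37, 0.062 and 0.12 on days 3, 7 and 10 (mean 0.18, SD 0.16, n = 3; exact sign-flip test, two-sided p = 0.25), so on days 7 and 10 most of the difference lies between the lost regions and the other 2 classes. The headers of the hypoxia replicate 1 files for days 7 and 10 name normoxia, and with the libraries of those days exchanged the log2 differences would be -0.28 and -0.57, leaving 1 of 3 days higher.

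**Figure D2:**
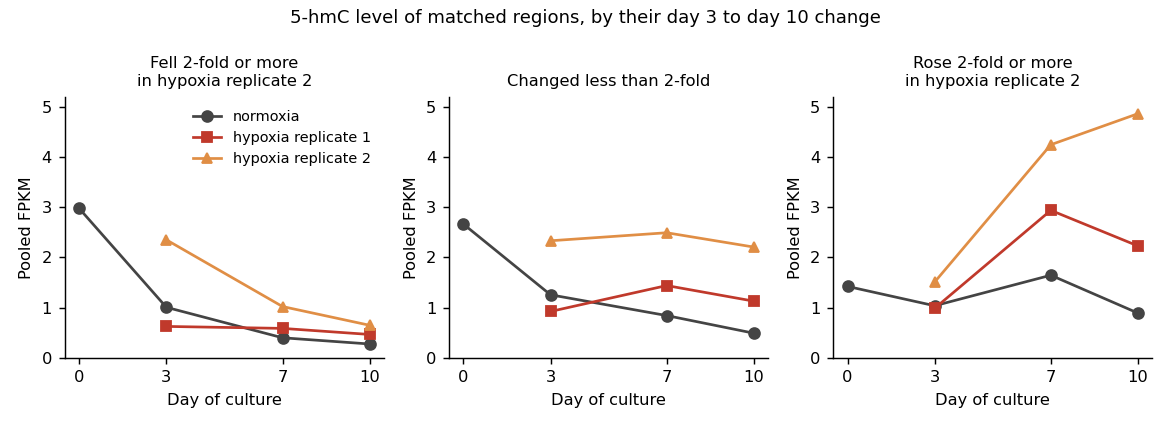
Pooled FPKM (vertical axis) by day of culture (horizontal axis) for 84728 lost, 59779 intermediate and 12134 gained regions, 1 point per library. The classes were set on hypoxia replicate 2 itself, over its own matched regions, so its direction between days 3 and 10 is given by construction; gained regions reach 2.94 FPKM in hypoxia replicate 1 and 1.64 in normoxia on day 7.

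The main comparison of the series is 1% against 21% oxygen. Averaged over days 3, 7 and 10, no window separated the oxygen levels. In limma, 0 of 24119 windows passed the threshold, with 807 at an unadjusted p under 0.05, and voom on the reads also gave 0. The smallest p belonged to a window with 0.548 kb of regions on chromosome 5, 2100001 to 2200000, at 1.05, 0.537 and 0.524 FPKM in normoxia and 2.40, 3.23 and 2.16 in hypoxia replicate 1 on days 3, 7 and 10 (log2 fold change 1.79 ± 0.26, limma adjusted p = 0.973). The other windows named by the rule were as small, with up to 0.696 kb of regions where hypoxia was higher and up to 0.257 kb where it was lower. Among single regions 0 of 367673 passed limma's threshold, with 12835 at an unadjusted p under 0.05 and 0 by voom. The region with the smallest p, at 41589224 to 41589557 on chromosome 8, was at 0.144, 0.734 and 0.573 FPKM in normoxia and at 1.60, 3.72 and 3.54 in hypoxia replicate 1 on days 3, 7 and 10 (log2 fold change 2.48 ± 0.43, limma adjusted p = 0.986). Without the normoxia day 3 library the window count was 819, of which 794 were higher in hypoxia. With normoxia and hypoxia replicate 1 exchanged on days 7 and 10 it was 896, of which 871 were lower in hypoxia.

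Windows were then tested for an oxygen effect that differs between days. In 719 windows the interaction of oxygen with day passed the threshold (limma moderated F), and in 621 of them hypoxia was lower on day 3 and higher on days 7 and 10. Over all tested windows 28.0% had that order. The 621 windows were already rich in 5-hmC on day 0, with a median of 2.74 FPKM against 0.954 for all windows. Their medians in normoxia were 1.63, 1.10 and 0.529 FPKM on days 3, 7 and 10, and in hypoxia replicate 1 they were 1.07, 2.07 and 1.60, an order for which these windows were picked. Over all tested windows the medians were 0.522, 0.458 and 0.387 FPKM in normoxia and 0.548, 0.469 and 0.461 in hypoxia replicate 1, which was thus not lower on day 3. The count was 2485 and 2393 without the day 3 libraries of hypoxia replicates 1 and 2. It was 0 without the term for replicate 2, 0 with quantile normalization and 0 among the upper part of the windows by mean FPKM (44, 1377 and 2055 at an unadjusted p under 0.05 in limma), 5 with voom and 15 in windows of 20 kb, and 3 of 26 splits of the libraries gave as many. Taken by day, 4 windows passed the threshold on day 3, 5 on day 7 and 1440 on day 10. These counts set 1 normoxia library a day against the hypoxia libraries. Their residual spread comes from the hypoxia replicates alone, so they hold no spread of normoxia and do not separate oxygen from that library. On day 10 the normoxia library had the smallest share of reads in the common regions (10.4%). How near its levels lie to those that background reads alone would give was not measured. In simulated reads, the fits for oxygen by day and for oxygen at day 10 also called more unchanged windows than the threshold is meant to allow. Of the 1440, 1393 were higher in hypoxia and 47 lower, and 1226 of the 1393 held at least 5 kb of regions, against 0 of the 47. Among all 24119 tested windows, 11213 held at least 5 kb of regions.

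The windows that passed on days 3 and 7 were higher in hypoxia and short, with 0.234 to 1.545 kb of regions, and are named after their values were seen. On day 3 they were 3 windows of chromosome 8, starting at 4900001, 115800001 and 138100001, and 1 of chromosome 13, starting at 86000001. The windows of chromosome 8 are listed at 0 FPKM in normoxia on that day and were at 1.46, 1.46 and 2.21 FPKM in hypoxia replicate 1. On day 7 the same windows were at 0.980, 1.68 and 1.01 FPKM in normoxia, against 0.478, 0.817 and 0.197 in hypoxia replicate 1. On day 10 they were at 1.60, 1.43 and 0.985 FPKM, against 0.473, 0.404 and 1.17. The window of chromosome 13 was at 0.329 and 1.5 FPKM (log2 fold change 2.18 ± 0.37, limma adjusted p = 0.0476). On day 7 the windows starting at 18500001 on chromosome 2 and at 37100001 on chromosome 11 are listed at 0 in normoxia and were at 1.62 and 0.634 FPKM in hypoxia replicate 1. On days 3 and 10 that of chromosome 2 was at 0.363 and 0.542 FPKM in normoxia, against 2.21 and 0.535 in hypoxia replicate 1. That of chromosome 11 was at 0.456 and 0.725 FPKM, against 0.277 and 0.358. The window of chromosome 5 with the smallest p for oxygen also passed on day 7 (log2 fold change 2.31 ± 0.32, limma adjusted p = 0.00402). On chromosome 19 the window starting at 35200001 was at 0.733 and 2.53 FPKM (1.65 ± 0.26, limma adjusted p = 0.0173), and on chromosome 10 the one starting at 102500001 was at 0.634 and 2.20 (1.69 ± 0.28, limma adjusted p = 0.0363). With voom the counts on days 3 and 7 were 0 and 0, with 297 and 626 windows at an unadjusted p under 0.05. With single libraries left out they ran from 2 to 400 on day 3 and from 6 to 1154 on day 7. The larger of these counts also held windows lower in hypoxia.

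The windows named for day 10 were chosen after their values were seen, from those with the smallest p and, where hypoxia was higher, at least 5 kb of regions. On chromosome 16 the window from 88500001 to 88600000, with 81.2 kb of regions, was at 4.32, 3.27 and 1.26 FPKM in normoxia on days 3, 7 and 10. It was at 3.68, 6.21 and 5.29 in hypoxia replicate 1 and at 5.39, 8.29 and 8.16 in hypoxia replicate 2 (day 10 log2 fold change 2.04 ± 0.23, limma adjusted p = 8.65e-05). The window from 89000001 to 89100000 on the same chromosome was at 3.87, 1.94 and 0.692 FPKM in normoxia and at 2.75, 3.98 and 3.35 in hypoxia replicate 1 (log2 fold change 2.08 ± 0.23, limma adjusted p = 8.37e-05). The window from 1200001 to 1300000 on chromosome 5 was at 0.571 FPKM in normoxia and 2.81 in hypoxia replicate 1 on day 10 (log2 fold change 2.18 ± 0.24). On chromosome 17 the window from 80100001 to 80200000 was at 0.644 and 2.75 FPKM, and on chromosome 9 the one from 139000001 to 139100000 was at 0.747 and 2.83. The lower windows were small. The one with the smallest p, on chromosome 7 from 13500001 to 13600000, held 0.234 kb of regions and was at 2.66 FPKM in normoxia and 0.202 in hypoxia replicate 1 on day 10.

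**Figure D3:**
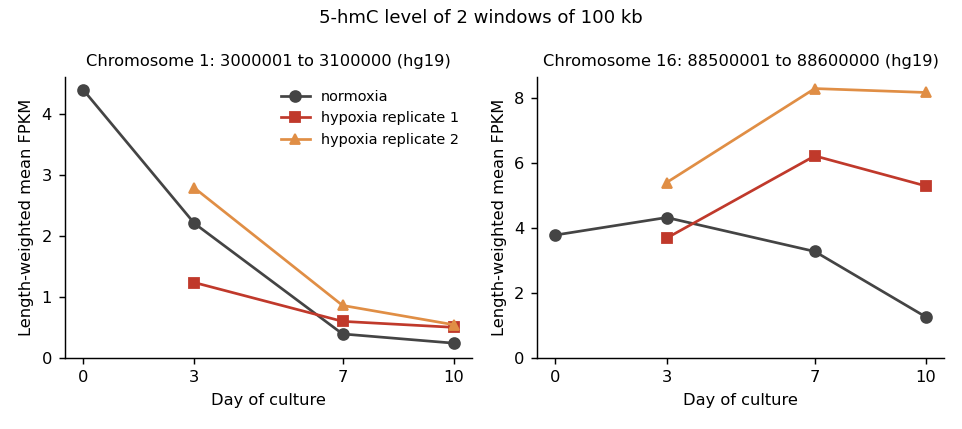
Length-weighted mean FPKM (vertical axis) by day of culture (horizontal axis) in a window of chromosome 1 (3000001 to 3100000) and one of chromosome 16 (88500001 to 88600000), 1 point per library. The chromosome 1 window is low in each series by day 10, while the chromosome 16 window stands at 1.26 FPKM in normoxia and at 5.29 FPKM in hypoxia replicate 1 on that day. Hypoxia replicate 2, measured over other regions, can be read along its own line only.

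The number of windows called on day 10 depends on how libraries are scaled. Quantile normalization left 0 windows for day 10 and 0 for oxygen by day, with 1862 and 1377 at an unadjusted p under 0.05 in limma. The smallest adjusted p for day 10 was then 0.0501. The 1393 windows higher in hypoxia went from a median log2 fold change of 1.32 (median SE 0.285) to 0.905 (0.286) and all kept their direction, while the prior degrees of freedom fell from 18.6 to 4.27. The 47 lower windows went from -2.34 (0.54) to -2.79 (0.51), so their calls ended without a smaller fold. With centring on the library median, the windows higher in hypoxia kept their direction at a median log2 fold change of 1.23. Their median SE was then 0.402 against 0.285. Centring on the library median left 313 for day 10 (260 higher, 53 lower) and 202 for oxygen by day, where the windows with a larger oxygen effect on days 7 and 10 than on day 3 went from 648 of 719 to 99 of 202. Without the term for replicate 2 the counts were 7 and 0 (914 and 44 at an unadjusted p under 0.05), and with voom 476 and 5. The day 10 count was 377 without the day 10 library of hypoxia replicate 1, 889 without that of replicate 2, and 3648 and 3166 without the day 3 libraries of replicates 1 and 2. The headers of the hypoxia replicate 1 files for days 7 and 10 name normoxia, so the direction on those days rests on the sample record, and with normoxia and hypoxia replicate 1 exchanged there the counts were 2 for day 10 and 0 for oxygen by day (1889 and 735 at an unadjusted p under 0.05).

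The windows higher in hypoxia on day 10 were unevenly spread over the chromosomes. They made up 21.8% of the tested windows of chromosome 22, 19.2% of chromosome 19, 12.9% of chromosome 16, 10.6% of chromosome 21 and 10.6% of chromosome 17. The shares were 2.77% on chromosome 4 and 3.09% on chromosome 5. Region reads on chromosome 22, relative to its share of region length, were 1.32 in normoxia on day 3 and 1.06 on day 10. In hypoxia both replicates moved the other way, by 0.0966 in replicate 1 and 0.109 in replicate 2 between those days. Chromosome 19 also differed in sign, with a change of -0.126 in normoxia, 0.0392 in hypoxia replicate 1 and 0.109 in hypoxia replicate 2. In normoxia this relative value drew closer to 1 on each autosome between days 3 and 10, for example from 0.780 to 0.934 on chromosome 4. Evenly spread background reads draw such values toward 1, and the share of reads in regions fell in normoxia over those days. The part of background in these changes was not tested. The signs in normoxia and hypoxia replicate 1 rest on the day 10 labels. With these exchanged, chromosome 22 would go from 1.32 to 1.28 in normoxia and from 1.18 to 1.06 in hypoxia replicate 1. Chromosome 19 would go from 1.49 to 1.53 in normoxia and from 1.49 to 1.36 in hypoxia replicate 1. On chromosome 21 the change was negative in each of the 3 series, at -0.304, -0.00281 and -0.194. The unevenness over chromosomes was not tested, and the length of regions per window was not taken into account.

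**Figure D4:**
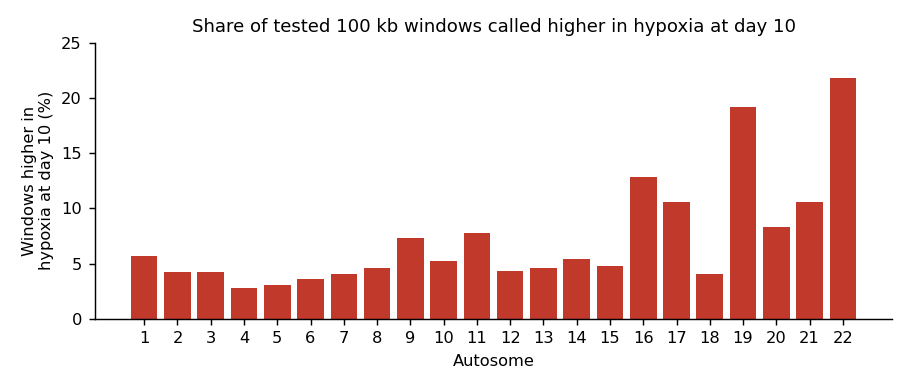
Percent of tested 100 kb windows called higher in hypoxia on day 10 (vertical axis) for each autosome (horizontal axis). Chromosomes 22 and 19 stand highest at 21.8% and 19.2%, and chromosome 4 lowest at 2.77%.

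Regions were also compared directly between hypoxia replicate 1 and normoxia by the rule of size, which compares libraries and not conditions. On day 3, 16332 of 91141 regions were at least 2-fold lower in hypoxia and 4938 higher, where Poisson sampling gives 1922 and 1992. On day 7, 24158 of 86840 regions were higher and 2533 lower, and on day 10, 30536 of 73552 were higher and 1973 lower. The counted regions as a whole were shifted between these libraries, by a median log2 of -0.255, 0.594 and 0.763 on days 3, 7 and 10, and the counts contain that shift. Of the 60130 regions counted on both later days, 11192 were higher on both, against 7525 for independent lists. Day 3 went against the later days, with 335 regions higher on both days 3 and 7 against 560 for independent lists, and 5963 lower on day 3 and higher on day 10 against 3587. The share of reads in regions was also lower in hypoxia on day 3 and higher on days 7 and 10.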

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

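The test of oxygen by day was planned, for genes; all other tests of explanations in this part were chosen after the results they bear on had been seen. The share of reads in regions moved in opposite directions on different days. Hypoxia replicate 1 minus normoxia was -3.19 points on day 3, 6.13 on day 7 and 6.79 on day 10. Each day has 1 library on either side, and the difference between days was not tested.

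On days 7 and 10, more background reads in normoxia might have diluted all regions alike, in which case 1 line would join the levels of any classes of regions in the 2 libraries. Between the second and the highest of the 4 classes of regions by day 0 level, hypoxia replicate 1 went from 0.832 to 1.26 FPKM on day 7 and from 0.802 to 0.964 on day 10, while normoxia went from 0.764 to 0.717 and from 0.687 to 0.392, so the slope there was -0.139 times (day 7; jackknife interval over 22 autosomes -0.336 to 0.0584) and -2.43 times (day 10; -4.07 to -0.785) the slope between the lowest and the second. This argues against a single dilution as the whole cause on both days, although the lost, intermediate and gained classes gave ratios of 1.03 on day 7 (1.01 to 1.06) and 1.12 on day 10 (1.03 to 1.21), and 0.951 and 1.07 when drawn at a log2 change of 2. The ratio of 1.12 differed from 1 by more than the 0.1 allowed for a single line, and the other 3 class ratios did not. A lower yield that acts evenly would be such a dilution, but one that acts unevenly cannot be told apart from less 5-hmC in normoxia, because no spike-in or input was used and the 10 highest regions, whose median on day 10 was 1.15 times as high in normoxia, go with either. Exchanged labels stay open as well, since on each of these days the headers name both normoxia and hypoxia replicate 1 as normoxia. Hypoxia replicate 2 on day 10 correlated across matched regions at 0.359 with normoxia and 0.552 with hypoxia replicate 1 (Spearman, difference -0.194). That is the order the sample record gives, but the larger share of reads in regions could give it by itself.

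On day 3 a single dilution is argued against by the order of the classes. Gained regions lay below intermediate ones in normoxia (1.04 and 1.25 FPKM) and above them in hypoxia replicate 1 (0.985 and 0.922), so the ratio of slopes was -4.17 (-8.63 to 0.293; -7.88 with classes at a log2 change of 2), while the classes by day 0 level gave 13.3 (-4.86 to 31.5), too wide to decide. An exchange of the day 3 labels cannot be told apart from a difference in the share of reads in regions. Hypoxia replicate 2 on day 3 correlated at 0.201 with normoxia and 0.0831 with hypoxia replicate 1 (difference 0.118), while its day 7 and day 10 libraries correlated less with normoxia on day 3 (0.304 and 0.318) than with hypoxia replicate 1 (0.336 and 0.354). An oxygen effect that changes with day stays open too, with its test over windows given next.

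In 719 windows the oxygen effect differed between days by limma's moderated F. Of 26 ways to choose 1 library a day as normoxia, 3 gave as many, so chance is not excluded. The highest other count was 1779, with hypoxia replicate 1 taking the place of normoxia on day 7, and 1572 came from doing so on days 3 and 7. Both keep the normoxia day 10 library in its place, but 6 other splits that keep it gave 0 to 71, and those that move it gave at most 54. For oxygen averaged over days the real count was 0 windows (807 at an unadjusted p under 0.05 in limma, 0 by voom), so that 80 of 80 splits gave at least as many by construction, and for day 10 against day 3 and day 7 against day 3 the same holds of 90 of 90 splits. These counts of splits decide nothing. The highest other count for oxygen was 896, with normoxia and hypoxia replicate 1 exchanged on days 7 and 10, the days on which 2 hypoxia headers name normoxia. The same 896 came from exchanging them on day 3 alone. Wrong labels and an oxygen effect that turns between days could both give this, and no value here tells them apart. The highest other count for each day contrast was 154. For single regions the 10 splits are too few for a share under 0.05, with 0 regions in the real split and 0 as the highest other.

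Reads on the mitochondrial genome, outside the chromosomes tested, stood out in 1 library. They made up 0.0942% of reads in hypoxia replicate 1 on day 10 (19944 reads), against 0.0118 to 0.0565% in the other 6 libraries over the common regions. Regions of the unplaced contig gl000220 held 0.261% of reads in normoxia on day 10, the highest of those 7 libraries, and 0.0963% in normoxia on day 0, the lowest.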

How the results depend on the processing

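The replicate term, pseudocounts, filters, scalings and left-out libraries were chosen before the data were examined; window sizes, the 5 kb minimum, voom, exchanged labels and the alternatives for shares and classes were added after seeing the data. Window counts below are by limma and stand against 4, 5 and 1440 for oxygen on days 3, 7 and 10, 719 for oxygen by day, and 0 for oxygen over all days, for day 10 against day 3 and for day 7 against day 3. Oxygen over all days stayed at 0 in 20 settings and moved in 2, and oxygen over single regions stayed at 0 in 14. Without the replicate term, which blocks hypoxia replicate 2, the count was 7 on day 10, 0 for oxygen by day and 1 for day 7 against day 3; it moved no other count by over 1.5 times. A pseudocount of 1 gave 20 on day 3 and 64 on day 7, and one of 0.01 gave 8 on day 3 and 265 by day. The upper part of the windows by mean FPKM gave 0 on day 3, 0 on day 7 and 0 by day (308, 1241 and 2055 at an unadjusted p under 0.05). Quantile normalization gave 0 on day 3, 0 on day 7, 0 on day 10 and 0 by day (736, 565, 1862 and 1377 unadjusted). Median centring gave 44, 19 and 313 on days 3, 7 and 10 and 202 by day; it removes median log2 shifts such as 0.17 for oxygen on day 7, 0.14 for oxygen over all days and -0.37 for day 10 against day 3. Windows of 20 kb gave 9 on day 7, 2823 on day 10 and 15 by day, and windows of 1 Mb gave 1, 99 and 564 on days 3, 7 and 10 and 422 by day, over other numbers of windows. Windows with at least 5 kb of regions gave 320 for day 10 against day 3, 0 on day 3, 0 on day 7 (144 and 1437 unadjusted) and 1213 by day. Voom on the reads gave 4650 for day 10 against day 3, 0 on day 3, 0 on day 7, 476 on day 10 and 5 by day. With normoxia and hypoxia replicate 1 exchanged on days 7 and 10 the counts were 896 for oxygen over all days, 1324 for day 10 against day 3, 44 for day 7 against day 3, 1 on day 7, 2 on day 10 and 0 by day (735 unadjusted). By construction that exchange turns the difference in reads in regions to -6.13 and -6.79 points on days 7 and 10 and that of gained over lost regions to a log2 of -0.28 and -0.57. Under quantile normalization the smallest adjusted p on day 10 was 0.0501, and the 1393 windows higher in hypoxia kept their direction at a median log2 of 0.905 against 1.32; the calls ended with a smaller fold and with prior degrees of freedom of 4.27 against 18.6. Under median centring the same windows kept their direction at a median log2 of 1.23, with a median SE of 0.402 against 0.285. The median shift that centring removes for oxygen on day 10 was 0.0995. The cause of the other changes was not tested. Leaving out 1 library at a time gave 0 to 819 for oxygen over all days (819 without normoxia day 3), 0 to 1370 for day 10 against day 3 (1370 without hypoxia day 3 replicate 1, 15 without normoxia day 3, 1 without normoxia day 10) and 0 to 834 for day 7 against day 3 (834 without normoxia day 3, 50 without normoxia day 10). Oxygen by day ran from 496 to 2485, with 2485 and 2393 without the day 3 libraries of hypoxia replicates 1 and 2. Oxygen on day 10 ran from 377 to 3648, with 3648 and 3166 without those libraries and 377 and 889 without the day 10 libraries of replicates 1 and 2. On day 7 the range was 6 to 1154, with 1154 and 443 without the day 3 hypoxia libraries, 32 without day 7 replicate 2, 56 and 52 without the day 10 ones and 8 without normoxia day 10. On day 3 it was 2 to 400, with 400 and 132, then 20 and 22 without the day 7 hypoxia libraries, 63 and 53 without day 10 replicates 2 and 1, and 2 without normoxia day 10. Over single regions it was 0 to 0. A left-out library leaves a group with 1 hypoxia library or no normoxia one; the lone library is assumed to vary like the others. The share of reads in regions differed by -3.41, 4.34 and 4.55 points on days 3, 7 and 10 over matched regions alone, and by 6.18 on day 7 without the 10 highest regions. Gained over lost regions differed by a log2 of 0.86 on day 3 with classes at a log2 change of 2, against 0.61. Not run, for want of an hg19 annotation, were the alternatives for genes, gene lists, promoters and shares of signal. Oxygen by day could not be fitted in the 6 common libraries alone. Without a normoxia library the F over both interaction terms could not be fitted, and the difference between the remaining days was not tested. For single regions the 6 libraries without a replicate term are already the design used. Single regions had a median of 3 to 5 reads in the common set, and depth and the spread between libraries were not separated as limits.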

Other observations

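The test of an explanation in this part, for chromosome 10, was chosen after the values had been seen, and the other values are descriptions. Long regions differed between the series in their share of the signal. The 41770 longest common regions held 49.1% of the region reads on day 0, and in normoxia 45.9% on day 3 and 26.5% on day 10. In hypoxia replicate 1 they held 36.8% on day 3, below normoxia, and 39.6% on day 10, above it. The 62755 longest regions of hypoxia replicate 2, over 974 bp, held 44.4% on day 3, 50.0% on day 7 and 52.4% on day 10, at 2.36, 2.73 and 2.58 FPKM, while the rest of its regions were at 1.47, 1.35 and 1.16 FPKM. Each value is that of 1 library.

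One of the 10 common regions with the highest mean level behaved unlike the other 9. The region at 41399520 to 41401356 on chromosome 17 was at 44.8, 37.8, 35.8 and 8.62 FPKM in normoxia on days 0, 3, 7 and 10, and at 14.9, 82.4 and 57.1 FPKM in hypoxia replicate 1 on days 3, 7 and 10. The other 9, of which 7 lie between 46386133 and 46428109 on chromosome 16 and 2 on chromosome 10, were lowest on day 0. The first of those on chromosome 10, at 42384277 to 42384585, was at 30.3 FPKM on day 0, at 76.5, 86.3 and 105 in normoxia and at 88.8, 70.6 and 80.4 in hypoxia replicate 1. Day 0, on which these 9 were lowest, had the largest share of reads in the common regions (39.0%). Whether their reads come from captured 5-hmC or from background was not tested.

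Hypoxia replicate 2 on day 3 correlated more with the starting cells than with the other day 3 libraries. Across matched regions its Spearman correlation was 0.467 with normoxia on day 0, 0.201 with normoxia on day 3 and 0.0831 with hypoxia replicate 1 on day 3, where regions are not independent replicates. Its day 7 and day 10 libraries correlated with normoxia on day 0 at 0.0577 and 0.00707.

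The change from day 3 to day 10 was shared more between the hypoxia replicates than with normoxia. Over 11213 windows with at least 5 kb of common regions, the log2 changes correlated at 0.54 between hypoxia replicates 1 and 2, at 0.27 between normoxia and replicate 2 and at -0.03 between normoxia and replicate 1 (Pearson, across windows, which are not independent). The differences between these correlations were not tested. Their order rests on the day 10 labels of normoxia and hypoxia replicate 1, which stay in doubt, and it was not worked out with those labels exchanged.

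Chromosome 10 held most of the regions with very high values in hypoxia replicate 2. Of 490 autosomal regions with a mean of at least 20 FPKM, 373 lay there, against a median of 2 on the other autosomes and 38 on the highest of them. Within the chromosome, 315 lay in the first 20 Mb, which is 4.45% of its 7076 regions, against 0.210% of the rest. They were short, with a median of 176 bp. A gain of the chromosome end might raise levels there, but it would raise all regions alike, and a factor of 6.59 would be needed to bring 4.45% of the regions to 20 FPKM. The median of the first 20 Mb was 1.22 FPKM, or 1.26 times the median of the other autosomes (1.11 to 1.38, bootstrap over 20 blocks), which argues against a gain as the cause of such values, while a small gain in part of the cells stays open. The design names no biological cause, and none other than a gain was tested.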
